A study of Canis lupus familiaris with 7 samples.

How the data were processed

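Total RNA of the left ventricle was extracted from dog hearts with Trizol, labelled with biotin after the array maker's procedure and hybridised to 1-colour Affymetrix canine arrays, per the labels' protocols. The 7 arrays cover 3 control samples and 4 samples of dogs on a diet with 0.5% sodium chloride for 2 weeks. The group and number of each sample were taken from its title. The deposited values are probe set intensity values on a linear scale, which per the submitters' processing notes came from GCOS, the array maker's software; its version, the way probes were summarised and the annotation used are not given in the sources used here. The 2% trimmed mean of the deposited intensity was 150 to 150.1 on every array, so each array had been scaled to a common mean. The array medians still differed by up to 0.93 on the log2 scale used below. Per the design text in the series record, the authors tested in Genetraffic by a t-test with variance stabilization and took an unadjusted p of 0.05 and a 2-fold change as their threshold.

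From the deposited intensity values, log2(value + 16) was computed and the arrays were quantile normalized, because their medians differed by more than 0.25, a limit set beforehand. The 111 control probe sets of the array maker were left out of the tests, and so was the third of the other 42924 probe sets with the lowest mean over all 7 arrays, without use of the groups. The remaining 28616 were tested with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3, low salt against control, without covariates since the labels give no batch, and p-values were adjusted by Benjamini-Hochberg. Changes are on the log2(value + 16) scale and understate those of dim probe sets. A probe set's error is its SE from that fit, and group values are given as mean ± SD. That SE uses a variance moderated over all tested probe sets, so it can be smaller than the probe set's own spread would give. Single array measures were compared by exact two-sided permutation over the 35 splits of 7 arrays into 3 and 4, which cannot give a p under 0.0571.

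Probe sets were named from the platform annotation. Of the 42924, 29254 have 1 gene symbol, 439 have several and 13231 are unnamed here. By gene number, 27680 of the 29254 matched the gene table of assembly UU_Cfam_GSD_1.0, all with the same symbol; for the others the platform's symbol was kept. That table served for names only, and no coordinates are given, since the build behind the array is not given in the sources used here. Of the tested probe sets 19670 have 1 symbol, 326 several and 8620 none. No gene was named from a probe set with several symbols. For the gene-level table of 11381 genes the probe set with the highest mean over all arrays stood for each gene, and for some of the genes named, not all, the values of further probe sets are given beside it.

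Before the data were examined, 44 gene lists were fixed from general knowledge of the heart, salt balance and cell types, together with the tests, the alternatives and the rule for named genes. The lists cover the renin-angiotensin-aldosterone system, superoxide sources, antioxidant defence, nitric oxide signalling, 6 areas of energy and lipid metabolism, fetal and hypertrophy genes, the sarcomere, calcium handling, ion and water transport, potassium channels, adrenergic signalling, matrix, inflammation, interferon response, complement and coagulation, immediate early, heat shock, glucocorticoid-responsive, circadian, hypoxia, protein turnover, apoptosis, cell cycle and ribosomal protein genes, and markers of 15 cell types. They were tested with camera at a preset correlation of 0.01 and adjusted over the 44, and again with the correlation estimated per list (statmod 1.5.0) and with fry. Fry passed 0 lists on balance; its test for changes in either direction, which does not compare a list with other genes, had adjusted p of 0.00178 for the inflammation and glucocorticoid lists and 0.00553 for the complement and smooth muscle lists. It was 0.0181 for the superoxide source and macrophage lists, 0.0268 for the immediate early list and 0.0389 for the nitric oxide list, so 8 lists passed it. No list was chosen on these samples.

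The named genes are, first, up to 12 genes higher and 12 lower with the largest change among probe sets with 1 symbol past an adjusted p of 0.05 whose groups did not overlap, 1 probe set per gene (that of smallest p). Where fewer than 12 were found, genes of smallest unadjusted p with at least a 2-fold change and no overlap filled the list, and are said not to have passed. For each list 2 to 4 genes, those of smallest p, were named, and 21 genes of the study's theme were named whatever their p. Genes named outside this rule are said to have been chosen after their values were seen.

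The alternatives fixed beforehand were offsets of 1 and 64, values as deposited, array medians set equal, no filter and array weights. Others were only probe sets of mean signal above the median, no trend, the replicate number as a block, and leaving out each sample in turn. Also fixed was a plain t-test with equal variances on the normalized values, without the authors' variance stabilization. An estimated correlation, fry and the mean of a gene's probe sets were the other alternatives fixed beforehand. Those chosen after seeing the data were leaving out control 4 and low-salt 3, the array median as a covariate, and counting per gene over the mean of its probe sets, which alters both the values and the units counted. The limma, camera and fry tests were run on simulated data with the real number of tested probe sets and arrays. The offset, normalization, filter and choice of probe set were not simulated. Over 20 simulations limma called 14.3% of 2-fold, 60.7% of 4-fold and 86.5% of 8-fold changes and 0.02% of unchanged probe sets. A list of 22 genes shifted by 0.4 was called in 20 of 20 simulations by camera, in 3 with an estimated correlation and in 13 by fry. The simulated noise was independent between probe sets and between arrays, whereas the real complement list had an estimated correlation of 0.074. These rates therefore do not show how limma or the list tests behave with correlated genes or with like arrays. Figures were drawn with matplotlib 3.10.9.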

Results

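The left ventricle of adult male mongrel dogs was profiled on Affymetrix canine expression arrays after 2 weeks on a diet with 0.5% sodium chloride and in control dogs. No salt content or feeding time is recorded for the control samples in the sample information used here. Each array held total RNA labelled as a heart sample, with 3 control samples (numbered 1, 3 and 4) and 4 low-salt samples (numbered 1 to 4). The design text speaks of 10 dogs on the diet, and how they relate to the 4 low-salt arrays, or whether RNA was pooled, is not given in the sources used here. The comparison asked which cardiac transcripts differ when dietary salt is low, and the title of the series relates it to mechanisms of heart disease. The array reads 43035 probe sets, short groups of probes aimed at 1 transcript, and 28616 of them entered the tests. Arrays carry no read depth, so the number of samples limits the precision. Changes are low salt minus control on the log2 scale of the signal plus 16, which understates the change of dim transcripts. The labels name each sample as a dog heart sample but do not say that every sample is a separate animal, so p-values measure the spread between these samples.

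A probe set for a lysozyme, a bacterial wall-degrading enzyme of phagocytes and body fluids, was among those that rose most in the low-salt ventricle. LYZ, the lysozyme gene among the macrophage markers, changed far less, as given below. The probe set of the lysozyme gene LYZF2 stood at 9.11 ± 0.84 (SD, n = 4) in low salt and at 6.51 ± 0.23 (SD, n = 3) in controls, a difference of 2.60 ± 0.38 (SE) and 6.07-fold, with a limma adjusted p of 0.0106. Apolipoprotein C1 (APOC1), a component of lipoproteins, rose by 2.38 ± 0.46 (SE, adjusted p = 0.0467), and the other APOC1 probe set was higher by 1.64 (adjusted p = 0.0755). NFKBIA, which encodes the inhibitor that holds NF-κB in the cytoplasm, rose by 1.88 ± 0.32 (SE, adjusted p = 0.0296). One probe set each of the actin crosslinker filamin A (FLNA, 2.46 ± 0.35), the nuclear membrane protein TMEM43 (2.22 ± 0.36), the ciliary transport protein IFT27 (1.91 ± 0.34) and the heme-binding protein HEBP1 (1.73 ± 0.33) rose as well, with adjusted p from 0.00991 to 0.0427. NUDCD1 rose by 1.12 ± 0.20 (SE, adjusted p = 0.0356) from the brightest control level of the group, 8.77 ± 0.22 (SD, n = 3). These 8 calls depend on single arrays, since 0 higher probe sets, LYZF2 included, passed without control 1. In each of these 8 genes all 4 low-salt values lay above all 3 control values, as the rule for naming them required.

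The other probe sets of these genes did not all move alike. For FLNA the brightest probe set differed by -0.72, against the rise of the dimmer one, and a brighter HEBP1 probe set differed by 0.01. Another IFT27 probe set differed by 1.08, and the 3 other NUDCD1 probe sets by 0.92, 0.44 and 0.40. Over 6 of the 8 genes with further probe sets, 12 in number, the median change was 0.40, and LYZF2 and NFKBIA have no other probe set. The FLNA, TMEM43, IFT27, NFKBIA and HEBP1 probe sets started from dim control signal, with median deposited intensities of 12, 2.7, 5.4, 22.3 and 13.5. ALDH5A1, the mitochondrial succinic semialdehyde dehydrogenase, C3H15orf40, the uridine phosphorylase UPP1 and FKBP15 had the next smallest p-values and did not pass, with changes of 1.44, 1.61, 1.54 and 1.65 and adjusted p from 0.0501 to 0.0694.

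The largest falls exceeded the rises, and most were seen in 1 probe set of their gene. A probe set for ATG101, part of the complex that starts autophagy, fell by 6.52 ± 0.49 (SE) from 11.17 ± 1.24 (SD, n = 3) to 4.65 ± 0.65 (SD, n = 4), with an adjusted p of 2.99e-05. Its low-salt signal lies at the floor (median deposited intensity 3.8), so the size depends on the offset, and the change ran from -8.20 to -4.98 over the settings tried. A probe set for SFT2D2 fell 48.6-fold on the normalized scale with the offset (adjusted p = 0.000199), also to a dim level (median deposited intensity 14.5). Falls were also found for FANK1 (-4.43), TBC1D8 (-3.80), EFCAB5 (-3.57), CTNNA3 (α-T-catenin of the intercalated disc, -3.26), HTR4 (a serotonin receptor, -3.22) and EIF1AX (a translation initiation factor, -3.21). TNFSF4 (the OX40 ligand), the ubiquitin ligase RNF185, DROSHA (the nuclease that starts microRNA processing) and SAE1 (a subunit of the SUMO-activating enzyme) changed by -3.01, -2.86, -2.86 and -2.85. Adjusted p for these 12 genes was at most 0.0467, and no low-salt value reached the lowest control value, as the naming rule required. Leaving out 1 control moved all 12 by over 1.5 times in fold, as in SFT2D2 (-4.98 without control 1 and -6.32 without control 4), FANK1 (-3.60 and -5.27) and EIF1AX (-2.41 and -4.18). With each of the 7 arrays left out in turn, ATG101, SFT2D2, FANK1 and TBC1D8 passed in all 7 fits, EFCAB5 in 3, CTNNA3, HTR4, RNF185 and SAE1 in 2, and EIF1AX, TNFSF4 and DROSHA in 1.

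The same 12 genes are read by 28 other probe sets, and 0 of these was lower by 2-fold or more. Their changes ran from -0.99 to 1.29, with a median of 0.01, and 1, for EFCAB5, was lower at an unadjusted p under 0.05. Over all 39 lower genes with another tested probe set, the called probe sets had a median change of -2.20 and the 77 others a median of 0.03 (quartiles -0.25 and 0.34). Of these 77, 4 were lower at an unadjusted p under 0.05 and 2 by at least 2-fold, and RANGAP1 (down to -1.14) and LOC480043 (down to -1.04), named after their values were seen, held 2 each of the 4. For the 6 higher genes with such probe sets, the 9 others had a median of 0.44 (quartiles 0.25 and 0.92). The plots of named genes per array and of probe sets of the same gene show both sides.

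**Figure D1:**
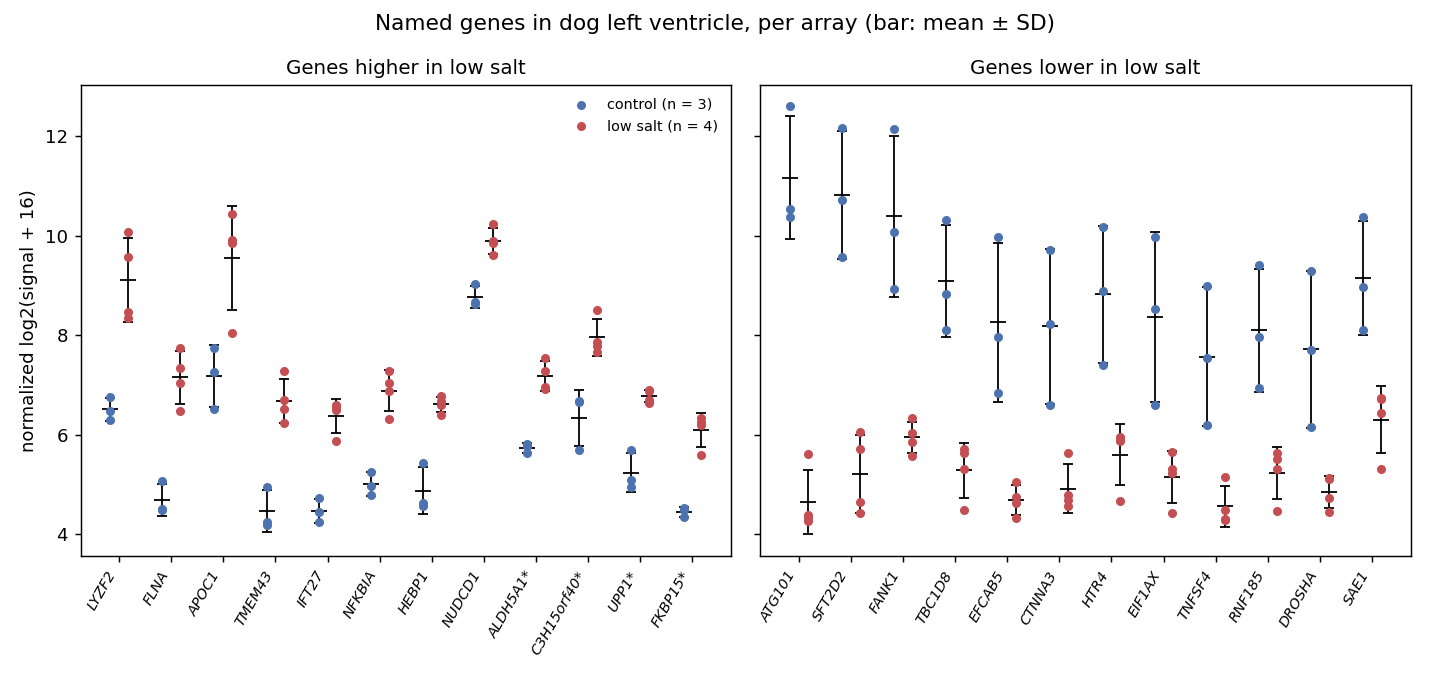
Normalized log2(signal + 16) of the genes with the largest changes on each array (points; blue, 3 control; red, 4 low-salt; bars, mean ± SD), with an asterisk for 4 genes that did not pass the adjusted threshold. LYZF2 lies between 8.35 and 10.07 in low salt and between 6.30 and 6.76 in controls, and ATG101 between 4.27 and 5.62 in low salt and between 10.37 and 12.60 in controls.

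**Figure D2:**
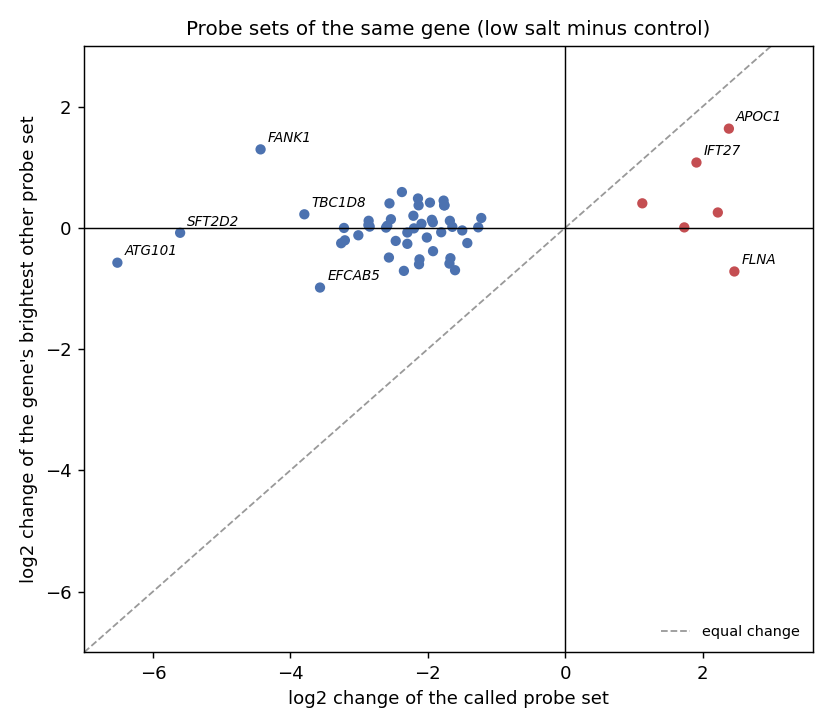
Log2 change (low salt minus control) of each called probe set with 1 gene symbol (horizontal) against that of the brightest other probe set of its gene (vertical). Some of these other probe sets, as for EFCAB5 and PVALB, were too dim to be tested. The line of equal change is dashed, blue points fell and red points rose. Most blue points lie near 0 on the vertical axis, whereas APOC1 and IFT27 lie at 1.64 and 1.08.

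Across the array 99 probe sets passed an adjusted p of 0.05 by limma, 11 higher (8 with 1 gene symbol) and 88 lower (50 with 1 gene symbol) in low salt. Of these, 4 higher and 59 lower ones changed at least 4-fold. At the threshold in the design text, an unadjusted p of 0.05 and a 2-fold change, 1260 probe sets passed, 479 higher and 781 lower. The methods' t-test gave 871 at that threshold, 312 higher and 559 lower, and 4 after Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was found for 3160 probe sets, 11% of those tested. The split between directions depended on the scaling: 38.0% of the probe sets past the design text's threshold were higher with quantile normalization, 5.8% with the values as deposited and 64.9% with array medians set equal, and of those past the adjusted p 11.1%, 7.9% and 23.7%. The 11 higher ones became 0 without control 1, 8 without control 3, 50 without control 4, and 2, 3, 13 and 1 without low-salt 1, 2, 3 and 4. The 99 became 21 without control 1, 41 without control 3 and 290 without control 4. They became 24, 26, 90 and 21 without low-salt 1, 2, 3 and 4. A count per gene over the mean of its probe sets, chosen after seeing the data, gave 12.

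Complement and coagulation genes stood higher together in low salt. Of the 33 genes of this list, fixed before the data were examined, 22 were tested, 18 had a change above 0 and 10 were higher at an unadjusted p under 0.05, against 0 lower. Their median change was 0.42 and their mean 0.46 (camera adjusted p = 0.000123 over 44 lists, and adjusted p = 0.679 with an estimated correlation). Tissue factor (F3), the starter of coagulation, differed by 0.83 ± 0.18 (SE), C1QB, a chain of the first complement component, by 1.01 ± 0.26, C6, part of the membrane attack complex, by 1.03 ± 0.28, and the central component C3 by 1.34 ± 0.39. Less bright probe sets differed by 0.91 for F3 and 0.85 and -0.02 for C6, and the 5 others of C3 ran from -0.62 to 1.32. These 4 and C1R (1.02, named after its value was seen) were the 5 that passed when adjusted over the list alone, and 0 passed over all probe sets. In 8 of the 22 genes the groups did not overlap, all higher, where chance gives 5.7% of genes over both directions and 10.6% of all genes showed it.

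Genes of inflammation and leukocyte recruitment were the other list past the threshold. Here 30 of 44 genes were tested, with a median change of 0.45 and a mean of 0.35 (adjusted p = 0.0457, and adjusted p = 0.679 with an estimated correlation). NFKBIA alone passed over all probe sets, and it was also the 1 gene that passed when adjusted over the list alone. The endothelial adhesion molecule E-selectin (SELE) differed by 1.42 ± 0.47 (SE) and interleukin 6 (IL6) by 1.10 ± 0.36, and both were higher in all 4 low-salt samples than in any control. Tumour necrosis factor (TNF) went the other way, by -2.19 ± 0.64 (SE, adjusted p = 0.246), while its 2 other probe sets, too dim to be tested, differed by 0.04 and 0.80, and that of SELE by 0.08. At an unadjusted p under 0.05 the list had 6 genes higher and 2 lower. By fry, which asks whether a list moves 1 way on balance, 0 lists passed, and both of these and the adrenergic list had an adjusted p of 0.0839. The median changes of these 2 lists stayed above 0 with the values as deposited (0.28 and 0.29) and with array medians set equal (0.71 and 0.72), but the inflammation list passed in neither scaling. The shift of all tested probe sets was 0.04 with quantile normalization, -0.18 as deposited and 0.26 with equal medians.

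A measure of RNA integrity lay apart between the groups, as these lists did. The GAPDH 3' to 5' signal ratio was 2.58 ± 0.18 (SD, n = 3) in controls and 2.27 ± 0.17 (SD, n = 4) in low salt, a separation without overlap (exact two-sided permutation p = 0.0571, the smallest that 35 splits allow). A second GAPDH pair of probe sets gave 29.3 ± 10.1 (SD, n = 3) and 17.7 ± 3.45 (SD, n = 4), with the same exact p of 0.0571. In both pairs the nearest arrays of the 2 groups were close, at 2.41 (low-salt 4) and 2.43 (control 1), and at 22.6 (low-salt 4) and 22.7 (control 4). The actin ratio did not separate the groups (exact p = 0.4).

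**Figure D3:**
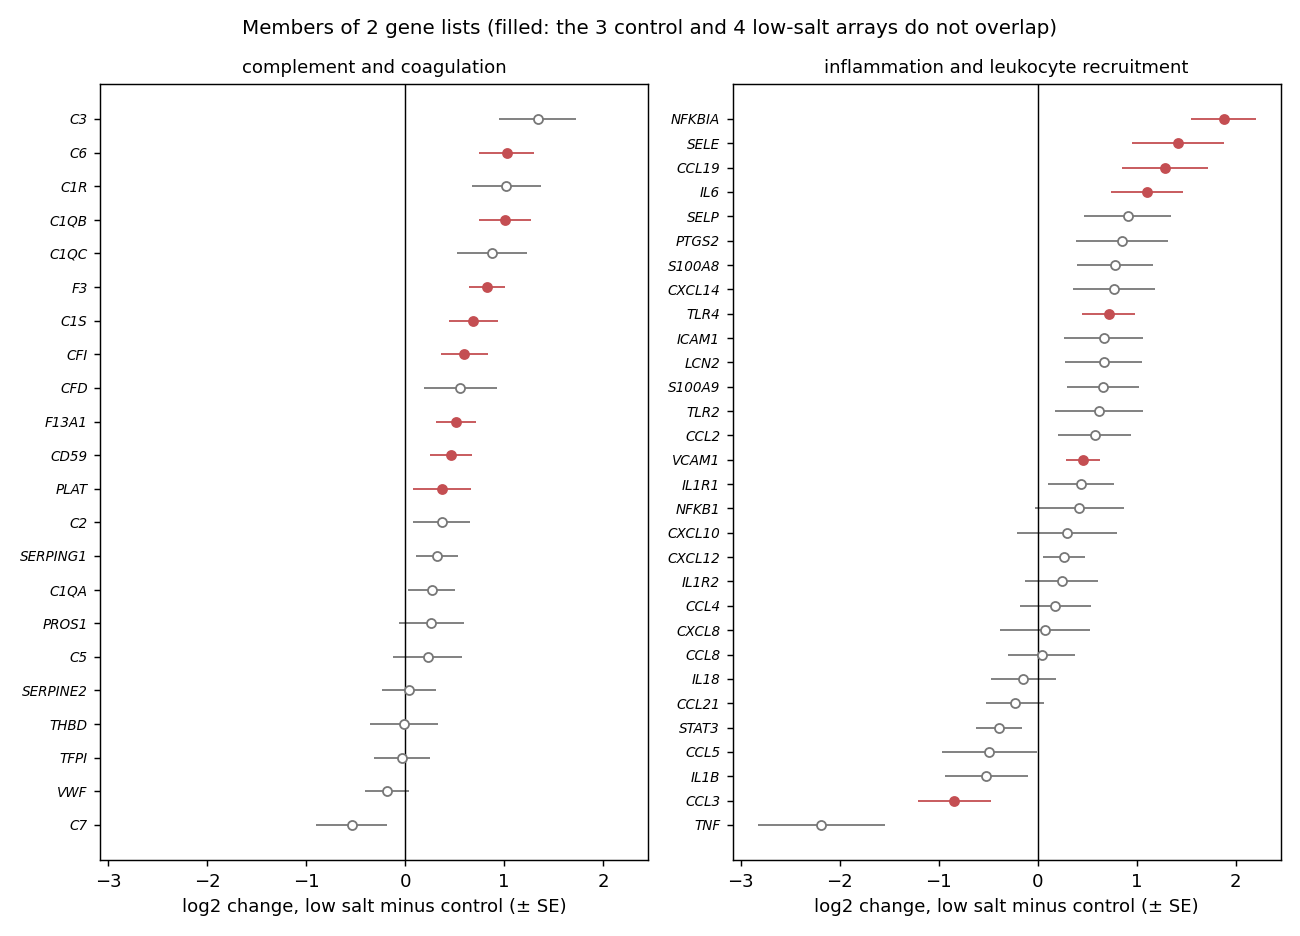
Log2 change (low salt minus control, horizontal, with SE bars) of each tested gene of the complement and coagulation list (left, 22 genes) and of the inflammation and leukocyte recruitment list (right, 30 genes); filled red points mark genes whose 3 control and 4 low-salt values do not overlap. C3 (1.34) and NFKBIA (1.88) head the lists, and TNF (-2.19) lies at the other end.

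The genes tied to the theme of the series, chosen before the data were examined, did not pass. Of 21 such genes 20 were named on the array and 18 were tested (AGT and SOD3 were too dim, and NPPA was not named), and 0 passed over all probe sets by limma or by the methods' t-test. At an unadjusted p under 0.05 stood 4 of them. PPARGC1A, the coactivator of mitochondrial biogenesis, differed by -0.74 ± 0.25 (SE, adjusted p = 0.301) and was lower in all 4 low-salt samples than in any control. The sarcoplasmic calcium pump ATP2A2 differed by -0.68 ± 0.26, the fatty acid transporter CD36 by -0.51 ± 0.22 and β-myosin heavy chain MYH7 by -0.86 ± 0.39, with adjusted p from 0.363 to 0.437. For ATP2A2 and MYH7 these came from less bright probe sets, and the brightest ones differed by 0.01 and -0.03. CD36 changed sign, to 0.07, with array medians set equal. The angiotensin receptor AGTR1 differed by 0.05 ± 0.33 (SE), ACE by -0.14 ± 0.42, the NADPH oxidase subunits CYBB, CYBA and NCF1 by 0.36, 0.05 and 0.36, and endothelial nitric oxide synthase NOS3 by -0.38 ± 0.41. Superoxide dismutase 1 (SOD1) differed by 0.70 ± 0.33, SOD2 by -0.34 ± 0.17, catalase (CAT) by 0.37 ± 0.21, CPT1B by 0.97 ± 0.63, PPARA by 0.33, PDK4 by 0.41, SLC2A4 by -0.11 and NPPB by 0.49 ± 0.59. These are the probe sets of smallest p, and others of the same gene differed: a far brighter one of PDK4 by -0.09, the brightest of SOD1 by 0.28, a brighter one of CYBA by -0.02, and the other ones of PPARA, SOD2, CPT1B and SLC2A4 by -0.34, 0.09, 0.41 and -0.01. Leaving out 1 array moved CPT1B to 0.22 (without control 4) or 1.64 (without control 3) and NPPB to -0.01 or 1.10 with the same arrays. The sign of AGTR1, ACE, CYBA, NCF1, SLC2A4 and PDK4 turned as well with 1 array left out.

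The wider lists around these genes held few members apart from the controls. In the renin-angiotensin-aldosterone list (11 genes tested, median -0.14, adjusted p = 0.697) the type 2 angiotensin receptor AGTR2 differed by -1.54 ± 0.43 (SE), without overlap, and was the 1 gene that passed when adjusted over the list alone, with ENPEP next at 0.67. Among NADPH oxidase and other superoxide sources (12 genes, median -0.02, adjusted p = 0.885) POLDIP2, a partner of NOX4, was the 1 gene that passed over the list alone (1.06 ± 0.26), and NOX4 itself differed by 0.74 ± 0.43. In antioxidant defence (26 genes, median 0.09, adjusted p = 0.272) 4 genes were higher at an unadjusted p under 0.05 and 0 lower. These were GPX3 (0.69), the mitochondrial peroxiredoxin PRDX3 (0.30), thioredoxin TXN (0.56) and PRDX6 (0.29), and 0 passed over the list alone. Nitric oxide and cyclic GMP signalling (21 genes, median -0.03, adjusted p = 0.697) held 2 higher and 3 lower genes at that level, among them arginase 2 (ARG2, -1.62 ± 0.49) and the phosphodiesterase PDE5A (-0.94 ± 0.36). The other probe sets of AGTR2 (too dim to be tested), POLDIP2 and ARG2 differed by -0.37, 0.12 and 0.73, the last against the sign of the one named.

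Energy metabolism showed no list past the threshold. Fatty acid uptake and oxidation (36 genes) had a median of 0.07 and an adjusted p of 0.988, with ACADS at 0.70 ± 0.23 (SE) but its brightest other probe set at -0.39, and PPARGC1A, CD36 and ACSL1 (-0.27) lower. Glycolysis and glucose use (32 genes) had a median of -0.03 (adjusted p = 0.819), with hexokinase 1 (HK1) at -0.74 ± 0.30 and LDHA at 0.21. The tricarboxylic acid cycle (19 genes) had a median of -0.04 (adjusted p = 0.809), with OGDH at -0.78 ± 0.32 and IDH3B at -0.40. Oxidative phosphorylation (43 genes) had a median of -0.02 (adjusted p = 0.868), and cytochrome c oxidase subunit COX8A, at -0.79 ± 0.19 and without overlap, was the 1 gene that passed over the list alone, while its 3 other probe sets lay between -0.14 and 0.05, and ATP5F1C was next at 0.31. Ketone body and branched-chain amino acid use (21 genes) had a median of 0.15 (adjusted p = 0.697), with the ketone-using enzyme OXCT1 at -0.88 ± 0.26 and BCAT2 at 0.71 ± 0.27. Cholesterol and lipid synthesis (25 genes) had a median of 0.06 (adjusted p = 0.868), with fatty acid synthase (FASN) at -0.97 ± 0.29 and FDFT1 at 0.48.

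The contractile and electrical genes of the ventricle stayed close to 0 as groups. Sarcomere genes (24 tested) had a median of 0.00 (adjusted p = 0.948), with LMOD2 at -0.49, desmin (DES) at 0.75, TCAP at 0.62 and MYOM2 at 0.66, and LMOD2 changed sign, to 0.09, with array medians set equal. Among fetal and hypertrophy genes (22 tested, median -0.01, adjusted p = 0.89) the atrial light chain MYL4 differed by -2.14 ± 0.65 (SE, adjusted p = 0.258) and XIRP2 by -0.49, though its other probe set differed by 0.36. Calcium handling (22 genes, median 0.02, adjusted p = 0.988), sodium, chloride and water transport (24 genes, median 0.01, adjusted p = 0.89), and potassium channels and gap junctions (14 genes, median -0.05, adjusted p = 0.868) held no gene past the threshold over the list alone. Their smallest p-values belonged to HRC (0.47) and PPP1CB (-0.52, with 0.40 in its other probe set), FXYD5 (0.60) and SCNN1A (-0.84), and the pair ABCC9 (-0.55) and KCNJ8 (0.49). In adrenergic and cyclic AMP signalling (18 genes, median 0.07, adjusted p = 0.697) the receptor kinase GRK2 differed by 1.18 ± 0.42, without overlap, and did not pass over the list alone, and its other probe sets differed by 0.12 and -0.43, while PDE4B differed by 0.76 and its other probe set by -0.46.

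Stress, growth and turnover lists did not pass. Immediate early and stress-activated genes (26 tested) had a median of -0.17 (adjusted p = 0.207) with members on both sides, PER1 at -0.94 ± 0.27 (SE), EGR2 at -0.94 ± 0.33, IER3 at 1.19 ± 0.41 and MYC at 1.10 ± 0.38. Glucocorticoid-responsive genes (18 tested) had a median of -0.21 (adjusted p = 0.697), and NFKBIA and PER1 passed over the list alone in opposite directions, though the 5 other PER1 probe sets ran from -1.06 to 0.64. Circadian clock genes (13 tested) had a median of 0.07 (adjusted p = 0.89), with PER1 lower, CLOCK at -0.97 ± 0.38 and CSNK1D at 0.91. Heat shock and protein folding genes (34 tested) had a median of 0.12 (adjusted p = 0.28), with HSPB2 at 0.93 ± 0.29 and HSP90AB1 at 0.37. Extracellular matrix and fibrosis genes (36 tested) had a median of -0.13 (adjusted p = 0.28), with SPARCL1 at 0.44 and COL4A1 at -0.49, the latter of the other sign, 0.08, with array medians set equal. Interferon response genes (30 tested, median -0.02, adjusted p = 0.747) had EIF2AK2 at -1.12 ± 0.43 and SP100 at -0.71, and hypoxia and angiogenesis genes (24 tested, median -0.00, adjusted p = 0.819) had adrenomedullin (ADM) at 0.52 and VEGFA at -0.43, which was 0.13 with array medians set equal. Ubiquitin-proteasome and autophagy genes (30 tested, median 0.07, adjusted p = 0.697) had MAP1LC3B, the autophagosome protein, at 0.43 ± 0.13 and cathepsin D (CTSD) at 0.57 ± 0.21. Apoptosis (17 tested, median 0.13, adjusted p = 0.885), cell cycle (25 tested, median 0.14, adjusted p = 0.868) and ribosomal protein genes (40 tested, median 0.03, adjusted p = 0.948) had FASLG (-0.86) and BIRC2 (0.38), AURKB (0.78) and MCM7 (0.70), and RPL26 (-1.46) and RPS9 (0.38) as members with the smallest p-values, and RPL26 passed over its list alone.

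Of 15 lists of cell type markers 0 passed. Macrophage and monocyte markers came nearest in the direction of the complement genes (18 tested, median 0.26, adjusted p = 0.173), with the scavenger receptor MARCO at 1.75 ± 0.62 (SE) and F13A1 at 0.52, and they share C1QA, C1QB, C1QC and F13A1 with the complement list. Mast cell markers lay lower (8 tested, median -0.25, adjusted p = 0.19), with the stem cell factor receptor KIT at -1.06 ± 0.34 and MS4A2 at -0.64, both without overlap. Ventricular cardiomyocyte markers had a median of -0.02 (15 tested, adjusted p = 0.868; TNNI3 0.25, MYOZ2 -0.16). Fibroblast markers had -0.02 (15 tested, adjusted p = 0.868), with PI16 at -1.52, against 0.62 in its other, dim probe set, and COL3A1 at -0.59. Endothelial markers had -0.07 (16 tested, adjusted p = 0.809), with KDR at 0.44 and EGFL7 at 0.43, and smooth muscle and pericyte markers 0.05 (15 tested, adjusted p = 0.697), the last with calponin (CNN1) at 1.19 ± 0.35 and DES as given above. Markers of T and NK cells (12 tested, median -0.04, adjusted p = 0.697), B and plasma cells (5 tested, median 0.21, adjusted p = 0.888), neutrophils (8 tested, median 0.08, adjusted p = 0.89) and erythroid cells and blood (5 tested, median 0.18, adjusted p = 0.948) did not pass. CD4 differed by -1.95 ± 0.46 in 1 probe set and by 0.06 in the other, and CCL5 differed by -0.49. In the other 3 lists the smallest p-values belonged to JCHAIN (-0.45) and FCRLA (0.63), S100A8 (0.78) and S100A9 (0.66), and KLF1 (0.56) and SLC4A1 (-0.46). Atrial or conduction tissue (10 tested, median -0.12, adjusted p = 0.28), nerve and Schwann cells (7 tested, median 0.07, adjusted p = 0.338), adipocytes (14 tested, median 0.09, adjusted p = 0.988), mesothelium and epicardium (5 tested, median 0.07, adjusted p = 0.885) and skeletal muscle (10 tested, median -0.12, adjusted p = 0.207) completed the set. Their smallest p-values belonged to NR2F2 (-0.75) and MYL4, MBP (-1.42) and NCAM1 (-0.57), LIPE (-0.79) and FABP4 (0.59), ALDH1A2 (-0.58) and BNC1 (-0.46), and TNNI2 and MYF5 (-2.55), and of these TNNI2 alone passed over all probe sets. Among the genes named for the lists, 1 array left out moved MYF5 to -1.15 (without control 1) or -4.06 (without control 4), CD4 to -1.38 or -2.58 and CCL5 to 0.13 or -1.01 with the same arrays. Without control 4 MYL4 moved to -2.89, ARG2 to -2.32 and COL3A1 to -1.21, without control 1 TNF to -1.53 and IER3 to 0.58, and without low-salt 4 MARCO to 2.45. The fast skeletal troponin TNNI2 fell by 2.38 ± 0.44 in 1 probe set (adjusted p = 0.0411), while the other differed by 0.59.

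Medians, means and the direction given by camera, which is relative to all genes, differed in sign for 11 lists. For fatty acid oxidation, sodium, chloride and water transport, cholesterol and lipid synthesis, B and plasma cells and adipocytes the median and mean were above 0 and camera pointed down. For circadian clock, nerve and Schwann cells and mesothelium and epicardium only the median was above 0. For glucocorticoid-responsive genes only the mean (0.01) was above 0, for NADPH oxidase the median alone was below 0, for ribosomal proteins the mean (-0.01) alone, and for no list did this concern a call.

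The arrays did not all lie with their groups. Control 4 correlated most closely with low-salt 3 (r = 0.947 over the tested probe sets), above its correlation with control 1 (0.901) and control 3 (0.919). Low-salt 1, 2 and 4 correlated with each other at 0.949 to 0.953 and with low-salt 3 at 0.924 to 0.93. The first and second principal components held 29.2% and 27.9% of the variance. Median deposited intensity was 39.6, 31.5 and 51.3 on control arrays 1, 3 and 4, and 21.8, 21.6, 44.2 and 19.3 on low-salt arrays 1 to 4 (exact two-sided permutation p = 0.171). Without control 4 and low-salt 3, an alternative chosen after seeing the data, 377 probe sets passed the adjusted p, 91 of them among the 99, and 2303 passed the design text's threshold. The complement list then had an adjusted p of 0.0324 at the preset correlation, and the inflammation list, whose median stayed at 0.45, had 0.0715.

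**Figure D4:**
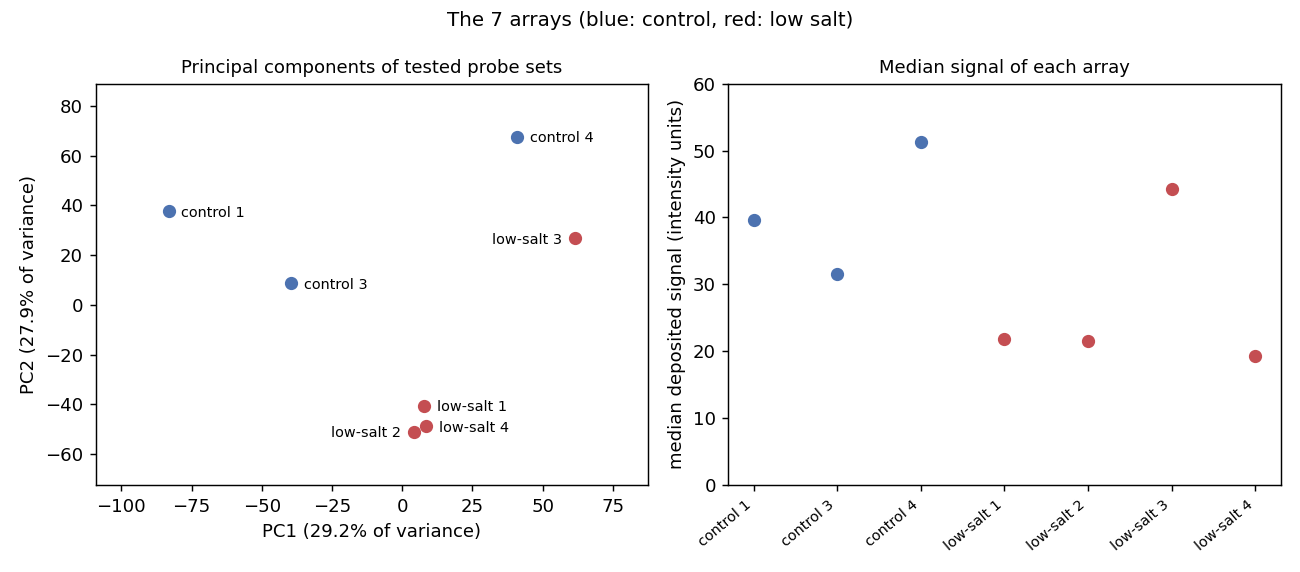
Left, the 7 arrays on the first 2 principal components of the tested probe sets (29.2% and 27.9% of the variance); right, the median deposited signal of each array in intensity units (blue, control; red, low salt). Low-salt 3 lies near control 4 on the left and has the highest low-salt median, 44.2, on the right.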

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

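The tests of the gene lists over other splits, of a swap and of dim background alone were set out before their results; all the other tests in this part were chosen after the result they bear on was seen, as was 1 change to the swap test named with it. Of 91 values of the low-salt group 5 had 1 sample far from the other 3, 5.5%, and chance gives about 1 in 20. IFT27 was lower in low-salt 3 (5.88) than in the others (6.49 to 6.60), a gap of 0.845 of the group's range. ATG101 was higher in low-salt 1 (5.62 against 4.27 to 4.38, gap 0.912 of the range), and HTR4 was lower in low-salt 2 (4.68 against 5.89 to 5.95, gap 0.949). CPT1B was lower in low-salt 3 (5.81 against 7.94 to 8.16, gap 0.905). The log2 array median was higher in low-salt 3 (5.91 against 5.14 to 5.24, gap 0.872).

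Other splits of the 7 arrays bear on the 3 counts. For the 99 probe sets past the adjusted p, 1 of 35 splits, the real one, gave as many, and the highest other gave 2. That is the most extreme rank that 35 splits allow, which makes chance less likely but does not exclude it. For the 1260 probe sets past the design text's threshold 2 of 35 splits gave as many, and chance cannot be excluded: the split of low-salt 1, 2 and 4 from the rest gave 1338. For the 2 gene lists 25 of 35 splits gave as many and the highest other gave 9, so chance cannot be excluded. The complement list's camera p of 2.79e-06 was exceeded in strength by 1 other split (1.08e-06), and the inflammation list's p of 0.00208 by others down to 0.000326, so 2 and 3 of the 35 splits were as low.

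The first pattern is the large falls of single probe sets such as those for ATG101 and SFT2D2. The other probe sets of the lower genes had a median change of 0.034 (quartiles -0.25 and 0.34) against -2.20. This argues against a fall of all transcripts under the diet where another probe set was bright. With means of 7.25 to 9.7, the brightest others changed by -0.575 (ATG101), -0.25 (CTNNA3), -0.206 (EIF1AX), 0.02 (SAE1), 0.116 (DROSHA) and 0.223 (TBC1D8). Dim ones near the floor, as for SFT2D2 (5.22) and FANK1 (5.26), could hardly show a fall. That of SFT2D2 changed by -0.082 and decides nothing. That of FANK1 rose by 1.294 (limma unadjusted p = 0.00596), against the fall of the called probe set. A fall of 1 transcript form stays open and was not tested. It stays open that 1 source of extra signal was present in the control preparations in different amounts, which may account for the falls: the order control 1 over 3 over 4 was found in 36 of the 59 falls of at least 4-fold, 61.0%, against 28.7% of 734 uncalled probe sets of like mean and spread, a ratio of 2.12 (the order was taken from these falls; of 10000 random sets of 59 of the 734, each with its own most frequent order, 0 reached 61.0%, over probe sets that are not independent). Higher unspecific signal on control arrays is a further candidate explanation, since 143 probe sets for olfactory receptors, sensory genes of the nose, had a median change of -0.479 (random sets of like signal, -0.103 to 0.111; -0.83 as deposited and -0.40 with array medians set equal), though this is far smaller than the falls themselves. A difference in RNA quality cannot be told apart from these candidates, since both GAPDH 3' to 5' ratios were higher on all control arrays. The second ratio (40.9, 24.4 and 22.7 on control 1, 3 and 4) and the spike-in mean signal (10453, 8374 and 5131) had that same order of controls. The first GAPDH ratio (2.43, 2.78 and 2.53) and the actin ratio did not. Probe sets with names in CfaAffx made up 77.3% of the lower calls and 47.2% of those tested (Fisher's exact p = 1.02e-08).

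The second pattern is the higher complement and inflammation genes. A larger share of macrophages in low salt as the whole cause is argued against by 14 macrophage markers in neither list. Their median change was 0.228 (quartiles 0.01 and 0.34), below the 0.42 of the complement list. The brightest of them were LYZ (0.20), MRC1 (0.12) and CD163 (0.22), while MARCO, also among them, rose by 1.75. A smaller share of the rise from macrophages, or a change in those present, stays open, since 10 of these 14 lay above 0 and the 4 complement genes that are macrophage markers had a median of 0.70 (4 above 0) against 0.37 in the other 18. Whether signal level of the arrays is the whole cause is not settled for either list. With the array median as a covariate the complement list kept its call by camera at the preset correlation (adjusted p = 0.00433). Leaving out control 4 and low-salt 3 gave 0.0324 but cannot decide, since the remaining array medians still separate the groups (39.6 and 31.5 against 21.8, 21.6 and 19.3). An estimated correlation, tried without the covariate, gave 0.679. The median of the inflammation list went from 0.45 to 0.31 with the covariate, and that list lost its call. A difference in RNA quality cannot be told apart from a response to the diet, which also stays open, because 0 control arrays overlapped the low-salt arrays in the GAPDH 3' to 5' ratio. The gap was narrow, from 2.41 on low-salt 4 to 2.43 on control 1, and in the second pair from 22.6 on low-salt 4 to 22.7 on control 4.

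The third pattern is the likeness of control 4 and low-salt 3. A swap of these samples is argued against by 368 probe sets that separate the other 5 arrays, those of the 377 called there that were also tested over all 7 arrays. Low-salt 3 lay nearer the low-salt mean in 87.0% of them, while control 4 lay nearer the control mean in 48.4%, so a wrong label of control 4 alone stays open. As first written, the swap test asked for over 90% on both arrays; that bound was replaced after the values were seen, because a swap needs both arrays out of place. Dim background alone is argued against by a correlation of 0.397 between the 2 arrays' deviations from their group means in the brightest 2862 probe sets (0.299 to 0.543 over 10 classes of signal). The high medians of both arrays may be related to the likeness, and no biological explanation was tested.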

How the results depend on the processing

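Leaving out control 4 and low-salt 3, the array median as a covariate and the count per gene were chosen after seeing the data. The 24 genes named for the largest changes kept their direction in all 19 settings tried for them, but most of the calls did not hold in most of them. Of the called rises LYZF2 held its call in 16, FLNA in 13, TMEM43 and NFKBIA in 9, IFT27 and NUDCD1 in 7, HEBP1 in 5 and APOC1 in 4. Of the falls ATG101 and SFT2D2 held in 18, FANK1 and TBC1D8 in 17, EFCAB5 in 10, CTNNA3, RNF185 and SAE1 in 9, HTR4 in 8, EIF1AX and TNFSF4 in 6 and DROSHA in 5. No gene held its call in all 19 settings, which include the plain t-test. The highest adjusted p over these limma and t-test settings was 0.218 for ATG101 and 0.248 for SFT2D2. The count past the adjusted p was 39 with an offset of 1, 76 with an offset of 64, 27 without the filter and 68 over probe sets above the median signal; the cause was not tested.

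The 99 probe sets past the adjusted p became 165 with the values as deposited, 177 with array weights, 19 without the trend and 4 by the plain t-test. They became 377 without control 4 and low-salt 3 and 32 with the array median as a covariate. Per gene over the mean of its probe sets, a setting that alters the values as well as the units, 12 passed. Of the 99, 95 were among the 165 and 91 among the 377. Leaving out each sample in turn gave 21 to 290, with 21 without control 1, 41 without control 3 and 290 without control 4. Without low-salt 1, 2, 3 and 4 it gave 24, 26, 90 and 21. The 11 higher ones became 0 without control 1, 8 without control 3, 50 without control 4, and 2, 3, 13 and 1 without low-salt 1, 2, 3 and 4. The 1260 past the design text's threshold became 1925 with an offset of 1, 215 with an offset of 64 (which shrinks the changes of dim probe sets), 2164 as deposited, 821 over the probe sets of mean signal above the median (fewer tested), 2303 without control 4 and low-salt 3, 2191 with the covariate and 306 per gene, and 1131 to 2092 when each sample was left out, with 2092 without control 4.

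The 2 gene lists became 1 with an offset of 64, 8 as deposited, 4 with array medians set equal, 1 over probe sets above the median signal, 0 with an estimated correlation, 0 by fry and 1 with the mean of a gene's probe sets, and 1 to 4 when each sample was left out (1 without low-salt 1 or low-salt 3, 4 without control 4), and 3 without control 4 and low-salt 3 and with the covariate. Both main calls are higher, but lower lists were called in some settings: 2 of the 8 as deposited, 1 of the 4 with equal medians, 1 of the 2 without the filter, 3 of the 4 without control 4, and 2 of the 3 in the last 2 settings. The complement list lost its call only with an estimated correlation and by fry, where its median stays 0.42 by construction, and its adjusted p otherwise ran up to 0.0324; leaving out each sample gave medians of 0.366 to 0.57. The inflammation list lost its call in 10 alternatives that keep all 7 arrays or leave out the like pair: its median was 0.231 with an offset of 64, 0.285 as deposited, 0.717 with array medians set equal, 0.293 without the filter, 0.419 over probe sets above the median signal, 0.448 with an estimated correlation, by fry and without control 4 and low-salt 3, 0.428 with the mean of probe sets and 0.31 with the covariate. It was 0.334 to 0.53 when each sample was left out, and its call was lost without control 3, control 4, low-salt 1 and low-salt 3. With array medians set equal 6 named genes reversed, CD36 to 0.072, LMOD2 to 0.087, COL4A1 to 0.083, PIK3R1 to 0.169, VEGFA to 0.131 and JCHAIN to 0.121, less than the shift of 0.26 in all probe sets. Where no cause is named, the cause was not tested.

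The replicate numbers gave no sign of pairing the samples. Deviations of same-numbered samples correlated at 0.074, -0.264 and -0.18 for numbers 1, 3 and 4, and 0 of the 3 control samples correlated best with its own number. The likeness of control 4 and low-salt 3 (0.434) bears on these values, so they cannot exclude a pairing. With the replicate block 27 probe sets passed the adjusted p, 23 of them among the 99, and 1188 passed the design text's threshold. The 2 lists kept their calls by camera at the preset correlation, the only list test run with the block.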

Other observations

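PVALB, CAPN3, DMD, TPM1, ACTA1 and NT5E are named here after their values were seen and form no tested group, and the fixed skeletal muscle and sarcomere lists did not pass (camera adjusted p = 0.207 and 0.948). The calcium buffer parvalbumin (PVALB) fell by 1.498 ± 0.284 (SE, limma adjusted p = 0.0439), the muscle protease calpain 3 (CAPN3) fell by 1.60 ± 0.30 (adjusted p = 0.0411), and single probe sets of dystrophin (DMD) and tropomyosin 1 (TPM1) fell by 1.64 and 1.27 (adjusted p = 0.0386 and 0.0411). The brightest DMD and TPM1 probe sets differed by 0.02 and 0.01, the other PVALB probe set by -0.04, and the 3 other CAPN3 probe sets, too dim to be tested, by -0.33, -0.70 and -0.68. Skeletal α-actin (ACTA1) differed by -0.05 in its brightest probe set and MYF5 by -2.55 ± 0.91 in 1 of 3, which became -1.15 without control 1 and -4.06 without control 4. The 2 probe sets of the atrial light chain MYL4 differed by -2.14 ± 0.65 and -1.70 ± 0.53 (adjusted p = 0.258 and 0.284), and those of the myosin heavy chain MYH4 by -0.82 and -0.68. NT5E, the ectoenzyme that makes adenosine, fell by 2.30 ± 0.29 in 1 probe set (adjusted p = 0.00368), while its brightest differed by -0.08.

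APOC1, IFT27 and NUDCD1 are the 3 higher genes with a second probe set higher at an unadjusted p under 0.05, and LYZF2 has a single probe set. Its rise was the largest in the main setting and not in every one: over the settings tried LYZF2 reached at most 2.86, against 3.94 for TMEM43, 3.68 for FLNA and 3.38 for IFT27, whose control signal was dim.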
